A study of Mus musculus with 10 samples.

How the data were processed

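Gene expression was measured on 10 single-channel Applied Biosystems microarrays, 5 hybridised with RNA from a pool of adult mouse retina and 5 with RNA from a pool of postnatal day 1 mouse cortex. Per the labels' protocols, tissue was kept in TRIzol, total RNA was extracted with the same reagent and checked on a gel and a Bioanalyzer, and 1 µg of total RNA was transcribed into digoxigenin-labelled cRNA for chemiluminescent detection. The groups were taken from the sample titles and source names, and the replicate number from the titles. The retina pool held 350 mice and the cortex pool 19 mice. The titles of the retina arrays include the letters P1, whose meaning is not given; the retina was taken as adult from the sample descriptions and the series text, and no age in days is given. The sample descriptions give the cortex mice as C57/B6, whereas the series text gives them as Swiss-Webster, and this conflict was not settled here.

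The deposited table holds 33012 probes and 10 arrays of positive linear intensity values, with 0 values at or below 0. The scanner software, background correction, normalization and detection calls behind the intensity values deposited by the authors were not given in the sources used here. No detection flag was used, so whether a dim probe lay above background was not tested. Signal medians per array, as deposited, are given in the report. For arrays, the number of arrays limits the precision.

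The values were put on the log2 scale. Array medians on this scale spanned 0.682, more than the tolerance of 0.1 set before the data were examined, so the arrays were quantile-normalized, which forces all 10 arrays to share 1 distribution. Probes were named from the platform annotation: 14411 had 1 gene symbol, 247 had several and 18354 were not listed there and stayed unnamed. Of the probes with 1 symbol, 14402 were matched by Entrez ID to a mouse RefSeq table, which changed 0 symbols. The annotation named 13840 genes, of which 540 had several probes. All probes of a gene had the same call in 426 of these, and in 1 gene, B4galt2, probes were called in opposite directions. In gene lists, the probe with the highest mean over the 10 arrays stood for a gene. No genome was used and no coordinates are given.

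Retina was compared with cortex with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, no covariates), 2-sided, with Benjamini-Hochberg adjustment over the 33012 probes. A probe was called when its adjusted p was under 0.05 and the difference was at least 2-fold. All differences are retina minus cortex on the log2 scale, and standard errors (SE) are those of limma after shrinkage. The spread of repeat arrays was taken as the SD of log2 values over the 5 arrays of a tissue. To compare tissues, each array was given its median absolute log2 deviation from the mean of the other 4 arrays of its tissue, and the 5 values per tissue were compared with an exact 2-sided permutation test over 252 assignments. Deviations within a tissue share arrays, so that p is approximate. Where an array was left out, the deviations of its tissue were rescaled for the smaller group, a correction made after the data were examined.

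For 24 gene lists fixed before the data were examined, limma's camera was run with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists, and 325 genes of the lists were measured (330 when a gene is counted once per list). The lists were rod phototransduction, photoreceptor structure and identity, cone photoreceptor, ribbon synapse, bipolar cell, amacrine and horizontal cell, retinal ganglion cell, Müller glia, retinal pigment epithelium, lens, cortical projection neuron, cortical interneuron, neural progenitor and radial glia, cell cycle, immature neuron and axon growth, glutamate and GABA receptor (with glycine receptor subunits), oligodendrocyte and myelin, microglia, erythroid, endothelial, fibroblast and meninges, glycolysis, oxidative phosphorylation, and reference gene. Genes to be named were fixed by rule: the 12 largest differences in each direction among called probes with 1 symbol whose replicates did not overlap and whose brighter tissue lay above the median of all probes, passing over predicted loci (0 were met in either direction), and up to 4 called members per list plus any called member against the direction of its list. This gave 106 genes. A member that was not called, or any other gene, is named only with its values, as an example chosen after its values were seen. A further 4 lists (pituitary, lens genes other than crystallins, choroid plexus, eye field transcription factor) and 88 families of genes that share a symbol prefix (at least 15 genes each) were looked at after the first results were seen, as was the brightness of 846 probes named for olfactory receptors, used as a yardstick for dim signal.

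The scripts were tested on simulated data for the retina and cortex comparison, with 33012 probes of which 200 were changed. Of the changed probes, 0% were called at a simulated 1.5-fold difference, 62% at 2.83-fold, 76% at 4-fold and 100% at 8-fold. Of the unchanged probes, 4 were called. The 2-fold minimum by itself holds back calls at 1.5-fold. In the data 8379 probes were called, far more than the 200 changed here. These shares therefore do not give the recovery in the real comparison. The list that had been shifted, glycolysis, was found, and 1 other list was also called. Gapdh and Pgk1 are in both the glycolysis and the reference gene list, so a call of the latter need not be false. Which list was called is not stated here, so the other call may be a false one. The alternatives tried were the values as deposited, median and 75th percentile centring, 2 planned filters on dim probes and 1 added after the data were seen, an offset before the log, other thresholds, other variance models, array weights, the replicate number as a block, leaving out each array, and other settings of the list test. Planned quantile normalization was already the setting used, so it gave no separate value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.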

Results

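The series measured transcript levels in 2 pooled mouse RNAs on an Applied Biosystems single-channel array, as part of a comparison of microarray platforms in which the cortex served as the reference RNA. One RNA came from retina described as adult (a pool of 350 mice, 5 arrays) and the other from cortex at postnatal day 1 (a pool of 19 mice, 5 arrays). The 5 arrays of a tissue were repeats of the same pool, so no p-value below measures the spread between animals. The limma and permutation p-values rest on the spread between arrays. The camera p-values set the genes of a list against all other genes and do not measure repeatability over arrays. Tissue also went with age, adult against newborn, and may have gone with strain, since the labels disagree on the strain of the cortex mice. Before normalization the median intensity per array was 836 to 987 in retina and 1255 to 1341 in cortex. On the log2 scale these medians were 9.80 ± 0.11 in retina and 10.34 ± 0.04 in cortex (SD, n = 5), a difference of -0.54 (exact permutation p = 0.00794, the smallest that 252 assignments of the arrays can give). The quantile-normalized values used below no longer carry that difference.

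The repeat arrays were run to show how much the platform varied on the same RNA. Repeat arrays of the retina pool varied more than those of the cortex pool. The median SD of a probe over 5 arrays was 0.332 log2 units in retina and 0.281 in cortex, and the 90th percentile was 0.873 and 0.762. The median deviation of an array from the other 4 of its tissue was 0.224 ± 0.012 in retina and 0.181 ± 0.013 in cortex (SD, n = 5), a difference of 0.0426 (exact 2-sided permutation p = 0.00794). Without the probes below the median brightness in both tissues, the difference was 0.0305 and no longer passed the threshold (exact permutation p = 0.0556). The spread depended on brightness. With the probes ranked by mean intensity into 10 equal bins, the median SD peaked in bin 4, at 0.649 in retina and 0.545 in cortex, and was 0.101 and 0.0735 in the brightest bin. Among bright transcripts with a small spread was Glul, which encodes glutamine synthetase, at 20.27 ± 0.03 in retina and 17.82 ± 0.07 in cortex (SD, n = 5). Among dim ones with a large spread was Bsn, which encodes the presynaptic scaffold bassoon, at 8.84 ± 1.08 and 8.89 ± 0.97. Across probes, which are not independent replicates, the Pearson correlation between arrays had a median of 0.966 over the 10 pairs of retina arrays (0.964 to 0.968), 0.974 over the 10 pairs of cortex arrays (0.973 to 0.976) and 0.875 over the 25 pairs of a retina and a cortex array (0.872 to 0.877).

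**Figure D1:**
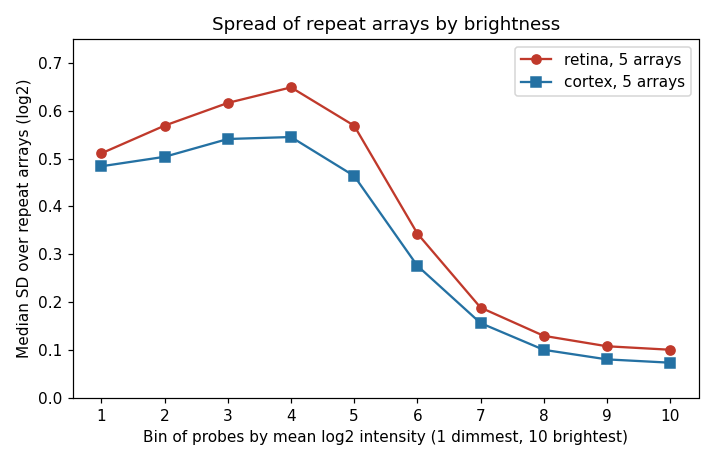
Median SD of log2 intensity over the 5 repeat arrays of each tissue (vertical axis), for 10 equal bins of the probes ordered by mean log2 intensity (horizontal axis), with circles for retina and squares for cortex. The spread is highest in bin 4 (0.649 in retina, 0.545 in cortex) and lowest in the brightest bin (0.101 and 0.0735).

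The comparison of retina with cortex shows how far the 2 RNAs differed on this platform. Of the 12 largest differences toward retina, 6 were genes of the rod phototransduction list and 4 of the list of photoreceptor structure and identity. Pdc (probe 925632), which encodes phosducin, a binding partner of the transducin beta and gamma subunits, had a mean log2 intensity of 20.48 ± 0.17 in retina and 8.91 ± 0.46 in cortex (SD, n = 5), a difference of 11.57 (SE 0.16, limma with Benjamini-Hochberg adjusted p = 2.29e-18). It was followed by Mgarp, a mitochondrial protein gene (11.40, SE 0.28), Gngt1, the rod transducin gamma subunit (11.19, SE 0.23), Guca1a, a guanylate cyclase activator (11.03, SE 0.16), and Rbp3, the retinoid-binding protein of the interphotoreceptor matrix (10.98, SE 0.16). Prph2, Pde6b, Mpp4, Cnga1, Kcnv2, Tulp1 and Cngb1 completed the 12, with differences from 10.84 to 10.55, and Mgarp and Kcnv2 were in no list. The transcripts most in excess in cortex were led by Dlx1 (probe 464971), a homeobox gene of forebrain interneurons, at 7.72 ± 0.72 in retina and 15.90 ± 0.03 in cortex (SD, n = 5), a difference of -8.18 (SE 0.25, limma with Benjamini-Hochberg adjusted p = 2.53e-14). Next were Gh, the growth hormone gene (probe 703036; -8.15, SE 0.19), Lmo3, a LIM-only gene (-7.78, SE 0.47), Neurod6, a transcription factor of cortical pyramidal neurons (-7.76, SE 0.16), and Mpped1 (-7.71, SE 0.14). Arpp21, Sox11, Nts (neurotensin), Igfbpl1, Dlx5, Fabp7 and Col3a1 completed the 12, with differences from -7.28 to -6.53. Col3a1 was at 7.21 on retina array 1 and at 9.37 to 9.88 on the other 4.

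In all, 8379 of the 33012 probes (25.38%) were called with limma, 3987 higher and 4392 lower in retina, and 348 were at least 16-fold higher and 217 at least 16-fold lower. Among the 14411 probes with 1 gene symbol, 2030 were higher and 2131 lower, and 4048 of the 13840 named genes had a called probe. The 5 values of one tissue all lay above the 5 of the other in 13358 probes, where chance gives 0.794% of probes. The first principal component, which held 67.8% of the variance, was followed by 4.86% for the second. Without normalization, the same test called 2474 probes higher and 7621 lower, with the median of all probes at -0.41, so the balance of higher and lower calls rests on the scaling. The dimmer tissue of all 12 largest genes higher in retina, and of 11 of the 12 lower (all but Fabp7), lay below the 95th percentile of the olfactory receptor probes. The same held for 75 of the 106 genes chosen for naming, among them Hk2, Gabrr2, Crb1, Rpe65 and Gabra5, so the size of these differences is set in part by dim signal that was not shown to lie above background. Of the 846 olfactory receptor probes themselves, 43 were called. Of the 330 members of the gene lists below, 48 lay below that percentile in both tissues, and for the 31 of these that were not called nothing can be read from the value. The rest of the 48 were called from signal as dim, and the counts of higher and lower members below include them. Examples are Cryga, at 9.68 in retina and 8.2 in cortex, and Notch1, at 8.89 and 9.98.

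**Figure D2:**
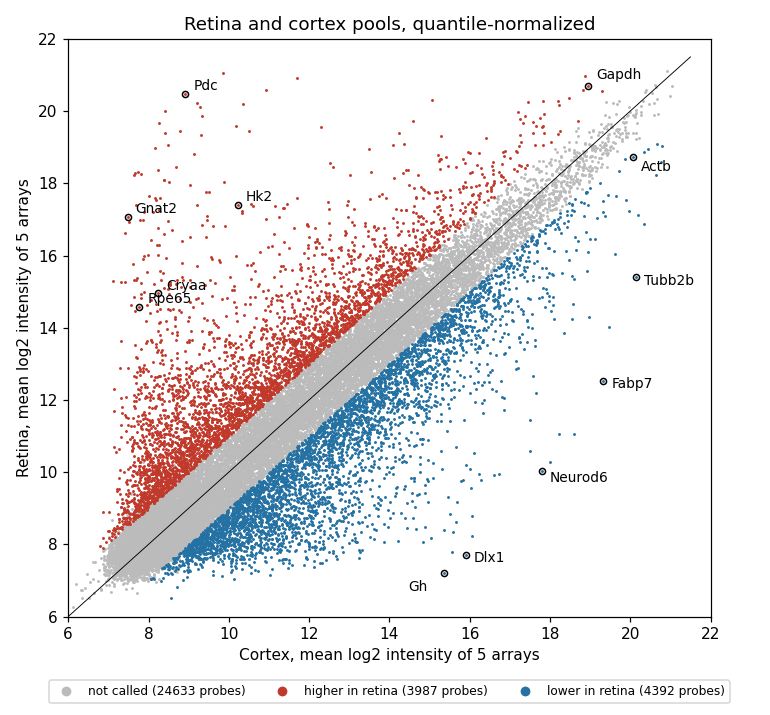
Mean log2 intensity of each probe over 5 retina arrays (vertical axis) against that over 5 cortex arrays (horizontal axis) after quantile normalization, with the line of equality and 12 genes circled. The 3987 probes called higher in retina lie above the line, the 4392 called lower lie below it, and Pdc and Dlx1 are among the farthest.

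Photoreceptor transcripts were higher in retina as a group. Of 16 measured genes of rod phototransduction, 14 were higher, 1 was lower and 1 was not called, with a median difference of 9.54 (limma camera, Benjamini-Hochberg adjusted p = 1.22e-08). Gnat1, the rod transducin alpha subunit, was at 20.58 ± 0.11 in retina and 10.92 ± 0.33 in cortex (SD, n = 5), and Pde6b, a rod phosphodiesterase subunit, was higher by 10.80 (SE 0.19). Guca1b, also among the 14, varied widely between retina arrays, at 16.76 ± 3.28 against 8.25 ± 1.14 in cortex (8.52, SE 1.1). Rgs9, which encodes the GTPase-activating protein of the rod and, in a longer form, of the striatum, went the other way, at 11.97 ± 0.20 in retina and 14.30 ± 0.07 in cortex, a difference of -2.33 (SE 0.086). Its partner gene Rgs9bp was not called (0.87, SE 0.35) and was dim in both tissues. All 19 measured genes of photoreceptor structure and identity were higher, with a median of 8.04 (camera adjusted p = 1.21e-14), among them the disc rim genes Prph2 (10.84) and Rom1 (9.23) and the transcription factor genes Nrl (9.66) and Crx (6.76). Of 12 cone genes, 11 were higher and Rxrg was not called (-0.92, SE 0.11), with a median of 6.05 (camera adjusted p = 1.66e-06). The cone transducin gene Gnat2 (9.60, SE 0.17), the short-wave opsin gene Opn1sw (9.53, SE 0.20), Pde6c (7.68, SE 0.16) and the cone arrestin gene Arr3 (7.47, SE 0.20) led this list.

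Synapse and inner retina transcripts followed. Of 11 ribbon synapse genes, 9 were higher and 2 were not called, with a median of 2.26 (camera adjusted p = 4.03e-06). Cabp4, a calcium sensor of photoreceptor terminals, and the complexin genes Cplx4 and Cplx3 were higher by 8.10, 8.10 and 6.03, and Egflam (pikachurin) by 5.94, while Pclo, which conventional synapses also use, was at 0.01 (SE 0.12). Bsn, the other gene not called, was below the 95th percentile of the olfactory receptor probes in both tissues. All 12 bipolar cell genes were higher, with a median of 5.61 (camera adjusted p = 6.86e-08), led by Cabp5 (8.11, SE 0.28), Scgn (7.52, SE 0.22), Lrtm1 (6.84, SE 0.15) and Grm6, the glutamate receptor of ON bipolar cells (6.60, SE 0.52). Grm6 was at 11.57 on cortex array 3 and at 7.7 to 8.33 on the other cortex arrays. Of 14 amacrine and horizontal cell genes, 11 were higher and 3 were not called, with a median of 1.75 (camera adjusted p = 1.5e-06). Pax6, Chat (choline acetyltransferase), Tfap2b and Calb2 (calretinin) were higher by 4.33, 3.63, 3.56 and 2.97, and Th, the dopamine synthesis gene tyrosine hydroxylase, was at 13.68 ± 0.11 and 13.66 ± 0.09. Of 11 retinal ganglion cell genes, 5 were higher and 6 were not called, with a median of 0.76 (camera adjusted p = 0.000854). Sncg (6.58, SE 0.17), Isl2 (4.40, SE 0.17), the heavy neurofilament gene Nefh (4.37, SE 0.095) and Rbpms (2.32, SE 0.16) were among the 5. Of 12 Müller glia genes, 8 were higher and 4 were not called, with a median of 3.06 (camera adjusted p = 2.47e-05). Crb1 (7.02), Abca8a (5.02) and the carbonic anhydrase genes Car2 (5.02) and Car14 (4.90) led, and the astrocyte and radial glia gene Slc1a3 was at -0.84 (SE 0.066), short of the 2-fold minimum.

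Genes known from tissues next to the neural retina were also higher. Of 12 retinal pigment epithelium genes, 7 were higher, 1 was lower and 4 were not called, with a median of 3.16 (camera adjusted p = 0.00202). The visual cycle gene Rpe65 was at 14.58 ± 0.14 in retina and 7.77 ± 0.40 in cortex (SD, n = 5), and Rgr (7.29), Rrh (5.86) and the pigment gene Dct (5.21) were higher too. Ttr, transthyretin, which the choroid plexus of the brain also makes, was lower in retina (-1.38, SE 0.058). Of 17 lens genes, 14 were higher and 3 were not called, with a median of 3.13 (camera adjusted p = 6.14e-07). The 14 were all crystallin genes, led by Cryaa (6.71, SE 0.29), Cryba1 (6.71, SE 0.18), Crygs (6.48, SE 0.13) and Cryba2 (5.61, SE 0.22). The 3 members that are not crystallins, Gja3, Mip and Bfsp1, were at 0.28 (SE 0.30), 0.03 (SE 0.48) and -0.58 (SE 0.27), with both tissues below the 95th percentile of the olfactory receptor probes.

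**Figure D3:**
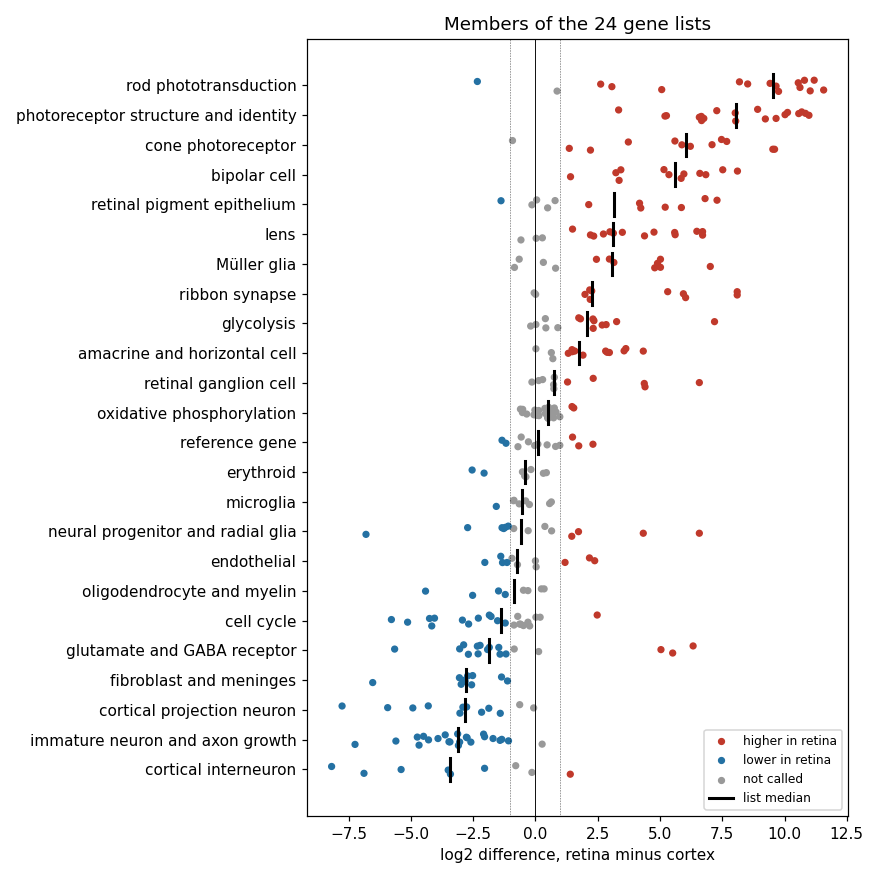
Log2 difference, retina minus cortex (horizontal axis), of each measured member of the 24 gene lists (vertical axis), with red points called higher, blue points called lower, grey points not called and a black bar at the list median. List medians run from -3.41 for cortical interneuron genes to 9.54 for rod phototransduction genes.

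Both lists named for cortical neurons were lower in retina as groups. Of 12 measured members of the cortical projection neuron list, 10 were lower and 2 were not called, with a median of -2.83 (limma camera, Benjamini-Hochberg adjusted p = 1.22e-07). Whether each member is specific to such neurons was not tested. Besides Neurod6, these included Bcl11b (-5.93, SE 0.13), Tbr1, a gene of early-born cortical neurons, at 12.66 ± 0.24 in retina and 17.58 ± 0.09 in cortex (SD, n = 5), and Emx2 (-4.30, SE 0.27). Of 9 cortical interneuron genes, 6 were lower, 1 was higher and 2 were not called, with a median of -3.41 (camera adjusted p = 0.00103). Dlx1, Dlx5 (-6.88), Sp8 (-5.39) and the somatostatin gene Sst (-3.50) were lower. Gad1, the GABA synthesis enzyme gene that inhibitory neurons of both tissues use, was higher in retina (1.40, SE 0.081), although without normalization its difference of 0.94 was under the 2-fold minimum, and Gad2 was at -0.14 (SE 0.059). Of 17 glutamate, GABA and glycine receptor genes, 12 were lower, 3 were higher and 2 were not called, with a median of -1.85 (camera adjusted p = 0.000423). Gabra5 was lower by the most (-5.65, SE 0.28). The 3 that were higher were Gabrr2 (6.33, SE 0.16) and Gabrr1 (5.51, SE 0.34), the rho subunit genes typical of bipolar cells, and the glycine receptor gene Glra1 (5.04, SE 0.24).

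Transcripts of growing neurons were lower in retina than in the newborn cortex. Of 23 measured genes of immature neurons and axon growth, 22 were lower and Dcc, dim in both tissues, was not called (0.27, SE 0.33), with a median of -3.09 (camera adjusted p = 1.18e-11). Sox11 (-7.24, SE 0.18), the doublecortin gene Dcx (-5.60, SE 0.28), Tubb2b (-4.74, SE 0.080) and Nnat (-4.67, SE 0.047) led. Of 22 cell cycle genes, 12 were lower, 1 was higher and 9 were not called, with a median of -1.37 (camera adjusted p = 3.29e-05). Rrm2, a subunit of ribonucleotide reductase, was at 8.08 ± 0.40 in retina and 13.86 ± 0.02 in cortex (SD, n = 5), and Ccnd2 (-5.13), Birc5 (-4.25) and Aurkb (-4.16) were lower as well. Bub1b, a spindle checkpoint gene, was higher in retina (2.48, SE 0.072), whereas its relative Bub1 was lower (-2.29, SE 0.25). The 14 neural progenitor and radial glia genes were divided, with 6 lower, 4 higher and 4 not called, a median of -0.58 and no shift of the list (camera adjusted p = 0.41). Fabp7, the fatty acid binding protein of radial glia, was at 12.53 ± 0.11 in retina and 19.33 ± 0.05 in cortex, and Tnc was at -2.72. The 4 that were higher, Prom1 (6.58), Pax6 (4.33), Msi1 (1.73) and Hes1 (1.46), include 2 that stand in retinal lists as well, Prom1 and Pax6.

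Lists of other cell types did not pass as a group, except connective tissue. All 10 fibroblast and meninges genes were lower in retina, with a median of -2.77 (camera adjusted p = 3.67e-05), led by Col3a1 (-6.53, SE 0.36), Ogn (-3.05, SE 0.21), Lum (-2.98, SE 0.40) and Col1a2 (-2.89, SE 0.086). Of 8 oligodendrocyte and myelin genes, 4 were lower and 4 were not called (median -0.84, camera adjusted p = 0.101). The lineage genes Olig1 (-4.41), Pdgfra (-2.52) and Olig2 (-1.21) and the tight junction gene Cldn11 (-1.48) were lower, although Cldn11 was below the 95th percentile of the olfactory receptor probes in both tissues and lost its call with an offset before the log (-0.79) and against a 1.5-fold difference, and the myelin gene Mbp was at -0.48 (SE 0.12). Of 8 microglia genes, Aif1 was lower (-1.57, SE 0.36), again from values that dim and not with the offset (-0.87), and 7 were not called (median -0.52, camera adjusted p = 0.313). Of 8 erythroid genes, Alas2 (-2.54, SE 0.30) and Hba-a1 (-2.06, SE 0.077) were lower and 6 were not called (median -0.40, camera adjusted p = 0.293), all 6 below that percentile in both tissues, so the median rests on probes not shown to carry signal. Of 11 endothelial genes, 3 were higher, 4 lower and 4 not called (median -0.72, camera adjusted p = 0.641). Slco1a4 (2.38, SE 0.20), the VEGF receptor gene Kdr (2.17, SE 0.061) and Ly6c1 (1.19, SE 0.079) were higher, Ly6c1 only after normalization (0.80 without it), and Cldn5 was lower (-2.03, SE 0.055). Cdh5 (-1.39, SE 0.49, limma with Benjamini-Hochberg adjusted p = 0.028) was dim in both tissues and lost its call on leaving out any of 6 single arrays, with a difference of -0.93 without retina replicate 3.

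Transcripts of glycolysis were higher in retina. Of 14 measured genes, 9 were higher and 5 were not called, with a median of 2.06 (camera adjusted p = 9.67e-07). The hexokinase gene Hk2 was at 17.41 ± 0.10 in retina and 10.22 ± 0.19 in cortex (SD, n = 5), where the cortex value is in the dim range, and Aldoa (3.26), Eno2 (2.84) and Aldoc (2.68) followed. Of 25 oxidative phosphorylation genes, 2 were higher, Ndufb8 (1.54, SE 0.12) and Sdhb (1.47, SE 0.40, dim in both tissues), and 23 were not called, with a median of 0.49 (camera adjusted p = 0.0072). That shift was not held with an estimated correlation (adjusted p = 0.0685) or without normalization (median 0.11, adjusted p = 0.373), where Sdhb also lost its call (0.98). Several genes often used as references for normalization differed between the 2 pools. Of 13 measured, 3 were higher, 2 lower and 8 not called (median 0.10, camera adjusted p = 0.364). Pgk1 (2.31, SE 0.052), Gapdh (1.74, SE 0.071) and Hprt (1.49, SE 0.064) were higher and Actb (-1.34, SE 0.066) and Rplp0 (-1.18, SE 0.052) lower, calls that held under each of the 3 other scalings tried, whereas B2m was at 0.10 (SE 0.054) and Rpl13a at -0.03 (SE 0.071).

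**Figure D4:**
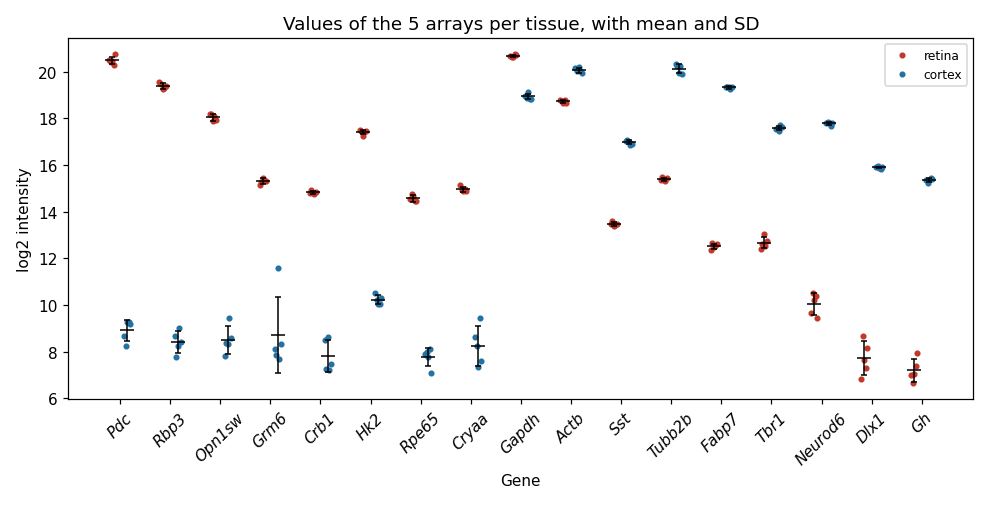
Log2 intensity after quantile normalization (vertical axis) of 17 genes (horizontal axis) on each of the 5 retina arrays (red) and 5 cortex arrays (blue), with bars for the mean and SD. The 2 tissues do not overlap in any of these genes, from Pdc (20.48 in retina, 8.91 in cortex) to Gh (7.21 in retina, 15.36 in cortex).

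Across the 24 lists, 18 passed the threshold in camera, 12 higher and 6 lower in retina, and 17 of them held with an estimated correlation, all but oxidative phosphorylation. The camera adjusted p-values of these 17 were then larger, from 0.000516 for photoreceptor structure and identity to 0.0356 for retinal ganglion cell genes. The very small p-values above thus rest on the preset correlation of 0.01. Calls adjusted over the list alone were the same as those over all probes for every list, with 0 of 330 members differing.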

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

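The single-array test of growth hormone and the test of 3 lens genes, both given among the other observations, were chosen only after their results were seen. In this part, the match of probes on values as deposited was added after the other results were seen, but before its own, and the other tests were chosen before. Among 216 groups of 5 values (each of the 106 named genes and the array medians and deviations, per tissue), 12 held 1 array whose gap to its nearest neighbour was over 0.71 of the whole range, where chance gives about 10.8. The gene values below are log2 intensities. In retina, Col3a1 was at 7.21 on array 1 against 9.37 to 9.88 on the others, Gnat2 at 17.23 on array 3 against 17.02 to 17.05, Pde6c at 15.40 on array 4 against 15.29 to 15.32, Egflam at 17.48 on array 3 against 17.25 to 17.31, and Hk2 at 17.24 on array 3 against 17.43 to 17.49. In cortex, Prph2 was at 10.96 on array 3 against 8.78 to 8.91, Grm6 at 11.57 on array 3 against 7.70 to 8.33, and Cdh5 at 9.01 on array 3 against 9.94 to 10.21. On cortex array 4, Fabp7 was at 19.24 against 19.34 to 19.36, Cldn11 at 8.36 against 9.42 to 9.65, Hba-a1 at 16.87 against 17.18 to 17.26, and Pgk1 at 15.40 against 15.52 to 15.56. Of these genes, Cdh5 and Cldn11 lost their calls in some settings, and the others kept theirs in all settings tried. Genes that were not named were not scanned, such as Guca1b of the rod list, at 16.76 ± 3.28 over the 5 retina arrays (SD).

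The larger spread between repeat arrays of the retina pool was tested against 2 technical explanations. Dimmer signal from the retina arrays was argued against by 7180 probes whose means as deposited lay within 0.25 log2 units of each other. Among them the difference in deviation of normalized values was 0.0479 (exact permutation p = 0.00794), 1.13 of that over all probes. With values as deposited it was 0.0525, or 0.87 of that over all probes. That p is the smallest the test can give, so it cannot register a reduction. The matched probes were not equated with all probes in brightness, on which the spread depends, so the ratios are only rough. A first match, on 8925 probes alike after normalization, gave 0.87. As deposited, those probes were still dimmer in retina by a median difference of -0.41, so the first match does not bear on dimmer signal. A single aberrant retina array was argued against too, since the highest exact permutation p on leaving out each retina array was 0.0159. With the filter at the median, which left median SDs of 0.152 in retina and 0.115 in cortex, the difference was 0.0305 and just missed the threshold (exact permutation p = 0.0556), while the median SD was higher in retina in each of the 10 brightness bins, including the brightest (0.101 against 0.0735). The pools themselves, their labelling and any order of hybridisation, which the labels do not give, stay open and untested.

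The number of called probes was compared with other splits of the 10 arrays into 5 and 5. Of 100 splits, only 1, the real one, called as many as 8379 probes and the highest of the others was 0. Every other split mixes the tissues, which puts the tissue difference into its residual spread and holds its count down, so this comparison does not measure chance. For the 18 gene lists past the threshold, 15 of the 100 splits gave as many and the highest other was 19. The 14 besides the real one all kept 4 arrays of a tissue together on one side and so held much of the tissue difference, and the 82 splits of 3 and 2 reached at most 13 lists. These splits too are not a measure of chance without a tissue difference.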

How the results depend on the processing

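All settings here were planned except a filter at the olfactory receptor 95th percentile, chosen after the data were seen, which called 6018 of 15143 probes. No setting called a probe in the direction opposite to the 8379. Without normalization, 2474 probes were higher and 7621 lower in retina, against 3732 to 4561 higher and 3972 to 4760 lower over the 3 other scalings (quantile, median and 75th percentile), because the median probe then stood at -0.41, and at 0.126 with median centring. An adjusted p alone, which drops the fold minimum, called 15704 probes, 7441 higher and 8263 lower. Leaving out single arrays gave 8280 to 8476. The replicate block gave 8398 called probes, 4000 higher and 4398 lower, and it ended no named call and changed no list. The deviations of same-numbered arrays correlated at -0.0202 to 0.0288, and 3 of 5 retina arrays were closest to their own number. Whether same-numbered arrays shared more than the number was not tested.

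Spread and correlation moved with the dim probes. The median SD in retina and cortex was 0.152 and 0.115 without probes below the median, 0.245 and 0.200 without those below the 25th percentile, and 0.203 and 0.170 with an offset before the log. The first of these filters left a spread difference of 0.0305 (exact permutation p = 0.0556) and the other settings kept it past the threshold; the cause was not tested. Correlations within retina, within cortex and across tissues were 0.981, 0.987 and 0.751 with the filter at the median and 0.982, 0.987 and 0.886 with the offset. With the filter at the 25th percentile they were 0.976 within cortex and 0.844 across tissues. Without normalization and with median centring they were 0.968 within retina and 0.973 within cortex (0.9677 and 0.9725). Leaving out single arrays gave a median SD of 0.303 to 0.332 in retina and 0.254 to 0.283 in cortex, lower where 4 values stand for 5, and a correlation within retina of 0.965 to 0.966 (0.9645 without replicate 3).

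Of the gene lists, 17 or 18 passed in every camera setting. Oxidative phosphorylation was lost without normalization (0.11, adjusted p = 0.373) and with an estimated correlation (0.49, adjusted p = 0.0685); the cause was not tested. The fry test, which asks whether genes of a list move and does not compare them with other genes, put all 24 past the threshold, adding neural progenitor (-0.58), oligodendrocyte (-0.84), microglia (-0.52), erythroid (-0.40), endothelial (-0.72) and reference genes (0.10). Without members shared with other lists, the reference gene median turned to -0.15 (adjusted p = 0.633). Named genes kept their call in 2418 cases and lost it in 17, for Gad1, Ly6c1 and Sdhb without normalization, Cldn11, Aif1 and Cdh5 with the offset, Cldn11, Cdh5 and Sdhb against a 1.5-fold difference, and Cdh5 at an adjusted p of 0.01, without the intensity trend and on leaving out 6 single arrays. Arrays gave no detection calls here, so signal over background limits what can be said of probes in the dim tissue.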

Other observations

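Transcription factor genes of the early eye field, a list looked at after the first results (Rax and Vax2 had been seen by then, and Pax6 and Lhx2 are in the fixed lists), were for the most part higher in the adult retina pool. Of 12 measured, 8 were higher than in cortex, 1 was lower and 3 were not called, with a median log2 difference of 4.05. Rax (8.14, SE 0.15) and Vax2 (7.85, SE 0.19) led, followed by Six6 (5.63, SE 0.18), Mab21l1 (4.62, SE 0.097), Tbx2 (4.13, SE 0.34), Mab21l2 (3.97, SE 0.12) and Six3 (2.10, SE 0.11). The cortex values of Rax, Vax2, Six6, Tbx2 and Mab21l2 lay below the 95th percentile of the olfactory receptor probes, so the size and order of these differences are not firm. Lhx2, which both tissues use in development, was lower in retina, at 12.74 ± 0.13 against 14.14 ± 0.11 (SD, n = 5; -1.41). Choroid plexus genes, another such list, were divided: of 8, 4 were higher (2 of them below the 95th percentile of the olfactory receptor probes in both tissues), 1 was lower and 3 were not called (median 0.47), with Kcne2 at 4.39 (SE 0.067), Folr1 at 1.67 (SE 0.090) and Igfbp2 at -1.88 (SE 0.053). Among 88 families of genes sharing a symbol prefix, 0 shifted with limma camera after Benjamini-Hochberg adjustment, the lowest adjusted p being 0.143, while 9 had an unadjusted p under 0.05, or 6 with an estimated correlation. In the kinesin family (Kif), 11 of 24 genes were lower and 0 higher, and in the Sox family 6 of 16 were lower and 0 higher. Other families leaned toward retina, such as Pde, with 8 of 19 higher and 3 lower, and Abhd, with 6 of 18 higher and 1 lower. For comparison, 2131 of the 14411 probes with 1 gene symbol were lower and 2030 higher. Sox3, Sox4 and Sox11, which were lower, are also in the fixed lists.

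Of the tests in the paragraphs that follow, the single-array test of Gh and the test of Mip, Gja3 and Bfsp1 were chosen only after their results were seen. Gh was the second-largest difference toward cortex, a tissue in which growth hormone is not a usual marker. Its retina mean of 7.21 lay below the 5th percentile of the olfactory receptor probes (7.439), so the size and rank of the difference are not firm. The Gh signal was on every cortex array, with the lowest cortex value 7.26 log2 units above the highest retina value. Gh was named by a rule that asks for replicates without overlap. The test of a single-array fault could therefore hardly have come out otherwise and gives no independent support. Pituitary tissue in the cortex pool stays a candidate source: 2 of 13 other pituitary genes were lower in retina, Pomc (-2.35, SE 0.35) and Cga (-4.07, SE 0.43), Prl was not called (0.31, SE 0.39), and Drd2, Scg2 and Chga, which neurons also express, were higher. For each probe by itself, cortex and retina were at 15.36 and 7.21 for Gh, 11.97 and 9.61 for Pomc, and 11.89 and 7.82 for Cga. Prl was below the median of the olfactory receptor probes in both tissues, so its value tells nothing, and 6 of the 8 pituitary genes not called, Prl included, lay below their 95th percentile in both. This lies between what was predicted with such tissue and without it, so pituitary tissue, cross-hybridisation of the probe (not tested) and a difference of tissue or age (not tested) remain open.

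The crystallin signal in the retina pool may come from lens tissue or from the retina itself. Of 9 measured lens genes that are not crystallins, 6 were higher in retina, with a median difference of 1.37, which met the prediction written for lens tissue in the retina pool. They were Tdrd7 (3.95), Slc2a1 (2.59), Lgsn (2.45), Prox1 (1.91), Hsf4 (1.37) and Npl (1.06). Prox1 is also in the fixed amacrine and horizontal cell list, and all but Lgsn are known outside lens. Lgsn and Hsf4 lay below the 95th percentile of the olfactory receptor probes in both tissues. The other 3, Lctl (0.81, SE 0.32), Foxe3 (0.62, SE 0.41) and Dnase2b (0.24, SE 0.40), were not called and were as dim in both tissues. Meeting the prediction therefore does not tell lens tissue from other sources. The largest difference of Mip, Gja3 and Bfsp1, 3 lens genes in the fixed list, was 0.28, but all 3 were that dim in both tissues too, so their values tell nothing. Crystallin transcripts made by the retina itself were not tested and remain open.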
